A study of Mus musculus with 8 samples.

How the data were processed

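Islets, the hormone-secreting cell clusters of the pancreas, were isolated from wild-type and Sting knockout mice aged 25 to 30 weeks, per the labels' protocols. They were picked by hand after collagenase digestion, recovered overnight in culture and then exposed for 3 h to DMSO, the solvent, or to DMXAA at 50 µg/mL. DMXAA is a small molecule that binds and activates mouse STING, the adaptor protein that carries the signal of cytosolic DNA to interferon genes. Poly(A)-selected RNA was made into cDNA libraries and read as paired ends on an Illumina HiSeq instrument.

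The deposited files hold 1 raw count per gene for each of 8 libraries, with 54532 Ensembl gene identifiers in each file. HISAT2, HTSeq and the mouse build mm10 are named in the submitters' processing notes, without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so how reads of overlapping and antisense genes were assigned is not known. The values were whole numbers whose totals differed between libraries, and no row held unassigned reads. Gene symbols and coordinates were taken from GENCODE release M21, which uses the same build and holds 54495 of the identifiers; the other 37 kept their identifiers only.

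Libraries were grouped by the genotype and treatment in their labels, which gave 4 groups of 2 libraries. Nothing in the labels says whether the 2 libraries of a group came from separate mice or from pooled islets, so p-values measure the spread between these libraries, which may be technical. Within each group the 2 libraries differed by more than sampling noise, with chi-square per degree of freedom between 7.41 and 59.8, so none was a copy of another. The count of Sting1 was not lower in the libraries labelled knockout, and these are therefore called knockout-labelled throughout.

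Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its default settings by group, which left 17055, and libraries were scaled by TMM. Every value in CPM, counts scaled to a common library size, was computed from the deposited counts with these scaled library sizes. A negative binomial model with 1 coefficient per group was fitted to all 8 libraries, which left 4 residual degrees of freedom, and contrasts were tested with the quasi-likelihood F-test with robust dispersion. The newer form of the fit was used (legacy=FALSE in glmQLFit), and the older form, the default of this version, was an alternative. The common dispersion corresponded to a biological coefficient of variation of 17.1%. Benjamini-Hochberg adjusted p-values under 0.05 were counted as changed. Standard errors (SE) of log2 fold changes were derived as the absolute fold change divided by the square root of the F statistic. The 5 contrasts were DMXAA against DMSO in each genotype, the difference between these effects (the interaction), and the genotypes against each other under DMSO and under DMXAA.

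A total of 30 gene lists for pathways, cell types and sex-linked transcripts was fixed before the data were examined, and 27 pathway and cell type lists had at least 3 tested members. Lists were tested with camera at its preset correlation of 0.01 between genes and again with the correlation estimated for each list, which allows for genes that vary together. Member counts are given over all genes tested and adjusted over the list alone. The genes named in the text followed a rule also fixed before the data were examined. They needed an official symbol, a mean of at least 1 CPM over the libraries compared, an adjusted p under 0.05 and no overlap between the libraries of the groups compared. For the interaction only the wild-type DMXAA and wild-type DMSO libraries had to be apart. The genes named for it were thus chosen partly on their wild-type effect. In the wild-type treatment contrast the 12 largest rises and the 8 largest falls were taken, and in each other contrast 8 of each. Up to 3 members of each list with the smallest p were added, and Sting1, Ins1, Ins2, Gcg, Ifnb1, Cxcl10, Adgre1 and Pax6 were added whether called or not. Not every gene that met the rule is reported here. Where all libraries of a group were at 0, a fold was computed against a floor of 3 counts over the group and is a lower bound. Floors and intervals cover counting error only, since reads copied by PCR are not independent molecules.

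The steps were also run on simulated data. Counts were drawn with real means and library sizes, and genes with an average above 1 CPM were changed in the simulated wild-type DMXAA group only. Of the genes changed 4-fold, 90 of 100 were recovered in the wild-type treatment contrast and 68 of 100 in the interaction. For genes changed 2-fold the numbers were 61 of 100 and 21 of 100. The wild-type contrast made 8 false calls among 159. In the simulated test of lists, a list of 30 genes raised by 1.5 times was called under both settings of camera. Of 26 unchanged lists, 1 was called with the preset correlation and 0 with the estimated one. Each gene was drawn independently from a mean profile shared by all libraries. Genes that vary together and differences in cell make-up between libraries were thus not simulated, and the false calls may be more frequent where these occur.

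The alternatives fixed before the data were examined were size factors by the RLE method, DESeq2 1.42.0, limma-voom, the older form of the edgeR test, no filter on low counts, a stricter filter of at least 1 CPM in at least 4 libraries, a fit of only the libraries compared, a minimum change of 2-fold, the replicate number as a block, and leaving out each library in turn. For the lists they included the directional test of fry. A covariate for the acinar marker sum and the comparison of knockout-labelled DMXAA with wild-type DMSO libraries were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

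Total counts ran from 15624020 to 19601850 per library. At these depths a gene with 0 counts in a library lay below 0.145 to 0.2 CPM. The insulin gene Ins2 alone took 11.48% to 18.62% of the counts, which lowers the depth left for other genes. Genes with near-identical copies, including Ins1 and Ins2, the Ifit3 pair, Tgtp2, the H2-Q genes, the Ifi200 cluster, Ccl3 and Ccl4, and the immunoglobulin constant regions, can share reads, and their values are uncertain to that extent.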

Results

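Poly(A) RNA was sequenced from primary mouse islets of wild-type and Sting knockout mice after 3 h with DMSO or with the STING agonist DMXAA. The design crossed 2 genotypes with 2 treatments, with 2 libraries in each of the 4 groups. Total counts were 18802114 and 18453519 in wild-type DMSO, 18709667 and 18207064 in wild-type DMXAA, 15624020 and 18500845 in knockout-labelled DMSO, and 19419236 and 19601850 in knockout-labelled DMXAA libraries. All means below are given with the SD over n = 2 libraries. Hormone transcripts made up a large share of every library. Ins2 took between 11.48% and 18.62% of the counts, and glucagon mRNA (Gcg) averaged 15641 ± 586 CPM in wild-type DMSO islets.

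The targeted gene was examined first. Sting1 (ENSMUSG00000024349, mm10 chromosome 18, 35733679 to 35740554, minus strand) had 39 and 41 counts in wild-type DMSO, 23 and 39 in wild-type DMXAA, 48 and 19 in knockout-labelled DMSO, and 35 and 27 in knockout-labelled DMXAA libraries. Its means were 2.03 ± 0.0243 CPM and 2.14 ± 1.5 CPM in the DMSO groups, with a log2 difference of 0.03 (SE 0.47, edgeR adjusted p = 0.984). Under DMXAA the difference was 0.00 (SE 0.49, adjusted p = 1). The count of the gene thus did not set the libraries labelled knockout apart from the wild type. The labels do not describe the allele, and a count over the whole gene does not show which exons the reads came from or whether protein was made. Directions drawn from genotype below rest on the labels.

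The first comparison asked what DMXAA did where STING was present. In wild-type islets the agonist raised interferon-stimulated genes and inflammatory cytokines within 3 h. Interferon beta mRNA (Ifnb1, chromosome 4, 88522025 to 88522774) had 0 counts in both DMSO libraries and 21.2 ± 10.8 CPM with DMXAA, at least 277-fold higher against a floor of 3 counts over the group. Of the 50 interferon-stimulated genes tested, 45 rose and all 50 did so adjusted over the list alone, with a median log2 fold change of 2.08. Their summed expression went from 875 ± 13 to 6153 ± 288 CPM. Among them Rsad2, an antiviral enzyme, went from 29.7 ± 1.83 to 1472 ± 36.5 CPM (log2 fold change 5.63, SE 0.33, adjusted p = 5.08e-06), and Ifit1, which binds viral RNA, went from 12.3 ± 1.68 to 439 ± 16.5 CPM. Ifit2 rose by 7.10, Oasl1 by 5.28 and Cmpk2 by 3.65 on the log2 scale. Ifit3 and its near-identical neighbour Ifit3b rose by 5.46 and 5.71, and the GTPase gene Tgtp2 by 5.38, although reads could be split between such copies.

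Cytokine and chemokine genes moved the same way. Of 24 tested, 14 rose, and 16 did so adjusted over the list alone, with a median log2 fold change of 2.01. The T cell attractant Cxcl10 (chromosome 5, 92346638 to 92348889) went from 5.37 ± 3.42 to 548 ± 37.2 CPM (log2 fold change 6.68, SE 0.40, adjusted p = 2.83e-05), and Ccl4, a monocyte attractant, from 0.439 ± 0.272 to 44.3 ± 8.7 CPM. Cxcl11 rose by 5.93, Ccl2 by 4.09 and Cxcl1 by 3.03. Tnf averaged 29 ± 20.5 CPM with DMXAA against 0.486 ± 0.131 CPM, and its call was lost without wild-type DMSO replicate 1 (adjusted p = 0.121), knockout-labelled DMXAA replicate 1 (adjusted p = 0.0925) or replicate 2 (adjusted p = 0.0873). Feedback genes rose in 6 of 12 cases, including Socs1, a brake on cytokine receptors, by 2.99, Cd274, which encodes the checkpoint ligand PD-L1, by 2.07, and Acod1, the itaconate-producing enzyme of activated macrophages, by 2.92. These lists kept their call with an estimated correlation, with adjusted p = 0.00822 for interferon-stimulated genes, 0.00128 for cytokines and 0.00822 for feedback genes.

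Several other immune and stress lists held a few called genes each. Of 21 NF-kB targets and inhibitors 4 rose, and 9 did so adjusted over the list alone. The inhibitors Tnfaip3 and Nfkbia rose by 2.24 and 1.62 (list median 0.53, adjusted p = 0.0722 with an estimated correlation). Of 19 genes of MHC class I and antigen processing 3 rose, and 11 did so over the list alone. The peptide transporter Tap1 went from 28.7 ± 0.946 to 63.8 ± 0.558 CPM (list adjusted p = 0.115 with an estimated correlation). The other calls, H2-Q7 and H2-Q4, were lost without wild-type DMXAA replicate 1 (adjusted p = 0.201 and 0.218), replicate 2 (0.0855 and 0.344) or wild-type DMSO replicate 1 (0.112 and 0.0979). Of 19 cGAS-STING pathway genes 3 rose, among them Ifi204 by 3.01 (list adjusted p = 0.267 with an estimated correlation). In the cell death list 3 genes rose and 1 fell. Ripk3, the kinase that starts necroptosis, went from 1.99 ± 0.238 to 55.6 ± 19.4 CPM (log2 fold change 4.80, SE 0.30, adjusted p = 7.92e-07; list adjusted p = 0.115 with an estimated correlation). In the stress response list 2 of 26 rose, Ppp1r15a from 94.7 ± 12.2 to 268 ± 52.9 CPM and Atf3 by 1.06, and the list itself was not called. Among immediate early genes, 1 rose and 1 fell out of 28, with Zfp36, which destabilises cytokine mRNAs, higher by 1.69.

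The largest falls in wild-type islets included a channel, a phosphatase and a vascular peptide gene. The potassium channel gene Kcnj2 (chromosome 11, 111066164 to 111076821) fell by 2.69 on the log2 scale, from 22.2 ± 0.207 to 3.42 ± 1.26 CPM (SE 0.35, adjusted p = 0.00115). Dusp6, which dephosphorylates ERK, fell by 2.16, from 64 ± 4.02 to 14.3 ± 4.15 CPM. The sulfotransferase gene Chst1 fell by 2.67 and the endothelin gene Edn1 by 2.14. Apln, which encodes the vascular peptide apelin, fell by 2.51, a call lost without wild-type DMXAA replicate 1 (adjusted p = 0.0654). Of 16 endothelial markers 3 fell, and 9 did so over the list alone, with a median of -0.46 and adjusted p = 0.237 for the list with an estimated correlation. All 3 lost their call without wild-type DMXAA replicate 1, with adjusted p = 0.0503 for Egfl7, 0.287 for Kdr and 0.338 for Eng. The summed endothelial markers were 1079 ± 182 CPM with DMSO and 769 ± 19.6 CPM with DMXAA. Markers of other cell types had negative medians as well, with -0.60 for fibroblasts (0 of 16 called, adjusted p = 0.37 with an estimated correlation), -0.89 for acinar cells (0 of 21, adjusted p = 0.669), -0.45 for macrophages (1 of 23, adjusted p = 0.53) and -1.74 for lymphocytes (1 of 13, or -1.60 with a gene at 0 set to its bound; adjusted p = 0.548). Plk2, a p53 target, fell by 1.40 (2 of 16 p53 targets fell; list adjusted p = 0.115 with an estimated correlation). The mitochondrially encoded mRNAs had a median of -0.55, and 1 of 12 fell (list adjusted p = 0.115 with an estimated correlation). That gene, mt-Nd4, lost its call in 5 of the 8 fits without a library, with a log2 fold change of -0.72 without wild-type DMXAA replicate 2. Its call was also lost with the acinar covariate, at -0.74 against -0.81 before (SE 0.18 in both fits, edgeR adjusted p = 0.0759). In the knockout-labelled islets the list median with DMXAA was -0.48 (adjusted p = 0.317 with an estimated correlation). The difference between labels had a median of 0.19 (adjusted p = 0.709 with an estimated correlation), so this list did not set the wild type apart.

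Genes of islet identity and secretion did not pass the test in this comparison. None of the 21 islet transcription factors, 38 genes of insulin secretion or 12 beta cell markers was called by edgeR, either over all genes or over the list alone. The log2 fold change was 0.14 for Pax6 (SE 0.15, adjusted p = 0.728), 0.07 for Ins2 (SE 0.31, adjusted p = 0.954), 0.63 for Ins1 (SE 0.30, adjusted p = 0.43) 0.12 for Gcg (SE 0.21, adjusted p = 0.847) and -0.31 for Sting1 (SE 0.47, adjusted p = 0.819). The macrophage gene Adgre1 was at 5.46 ± 1.73 CPM with DMSO and 2.4 ± 0.354 CPM with DMXAA (log2 fold change -1.17, SE 0.36, adjusted p = 0.218), and it passed the test without wild-type DMSO replicate 2 (adjusted p = 0.0484).

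**Figure D1:**
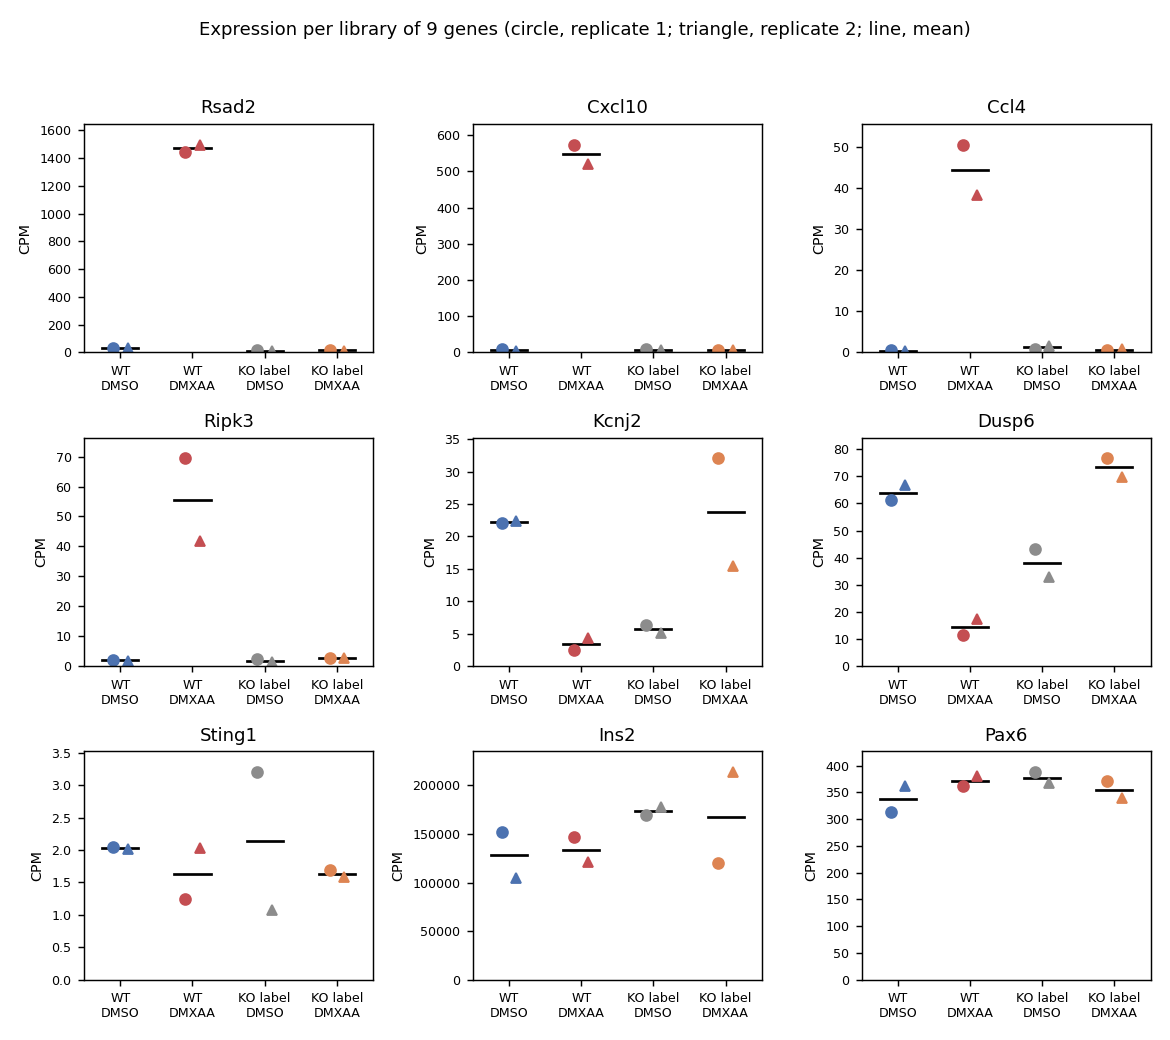
Expression in CPM (vertical axes, starting at 0) of 9 genes in each library by group (horizontal axes), with a line at the mean of the 2 libraries. Rsad2, Cxcl10, Ccl4 and Ripk3 stood high in the wild-type DMXAA libraries (mean 1472 CPM for Rsad2), Kcnj2 and Dusp6 were lowest there, Sting1 did not separate the genotype labels, and Ins2 and Pax6 varied without a called change.

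In total 253 of 17055 genes changed in wild-type islets by the quasi-likelihood test, 189 higher and 64 lower, and 210 of them by at least 2-fold. Camera called 16 lists, of which 3 held with an estimated correlation and 11 with fry. Acinar markers, a sign of exocrine tissue carried along with the islets, summed to 7609 and 1579 CPM in the wild-type DMSO libraries and to 1792 and 3302 CPM in the wild-type DMXAA libraries. The count of changed genes moved with single libraries. It was 168 without DMSO replicate 1 (126 higher and 42 lower), 994 without DMSO replicate 2 (536 and 458), 160 without DMXAA replicate 1 (140 and 20) and 163 without DMXAA replicate 2 (131 and 32).

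The second comparison asked what DMXAA did in the knockout-labelled islets. Interferon and cytokine genes did not pass the test there. None of the 50 interferon-stimulated genes was called over all genes or over the list alone, with a median log2 fold change of 0.24, and their sum was 809.9 ± 80.3 CPM with DMSO and 829 ± 94.4 CPM with DMXAA. Camera called this list upward (adjusted p = 0.048), a call not held with an estimated correlation (adjusted p = 0.686). None of the 24 cytokine genes was called. Cxcl10 was at 7.61 ± 2.44 and 5.58 ± 0.192 CPM (log2 fold change -0.44, SE 0.39, adjusted p = 0.92). Ifnb1 had 1 and 0 counts with DMSO and 3 and 0 with DMXAA. The log2 fold change was 0.10 for Gcg (adjusted p = 0.982), -0.09 for Pax6 (0.978), 0.14 for Ins1 (0.982), -0.06 for Ins2 (0.994), 0.61 for Adgre1 (0.785) and -0.34 for Sting1 (0.97).

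Of the genes that changed in knockout-labelled islets, 28 were higher and 36 lower with DMXAA. Ighg2c, an antibody constant region that shares reads with its relatives, was at 15.2 ± 6.64 CPM with DMSO and had 0 counts with DMXAA, at least 186-fold lower. The B cell surface gene Ms4a1 fell by 5.34 on the log2 scale, and 4 of 13 lymphocyte markers fell, 10 of them over the list alone (median -4.51, or -4.43 with a gene at 0 set to its bound; adjusted p = 0.223 with an estimated correlation). The sum of lymphocyte markers was 138 and 104 CPM in the knockout-labelled DMSO libraries, and between 9.58 and 55.4 CPM in the other 6. Among the rises, Kcnj2 rose by 2.07, the serine protease gene Prss23 by 1.46, Jag1, a Notch ligand, by 1.15, Cd93 by 1.08, the VEGF receptor genes Kdr and Flt1 by 0.97 and 1.04, and their co-receptor Nrp1 by 1.09. Without knockout-labelled DMSO replicate 2 the adjusted p was 0.458 for Kcnj2, 0.408 for Prss23, 0.59 for Jag1, 0.458 for Cd93, 0.338 for Kdr, 0.594 for Flt1 and 0.578 for Nrp1. The calls of Ighg2c and Ms4a1 were lost without wild-type DMSO replicate 1 (adjusted p = 0.06) and knockout-labelled DMXAA replicate 1 (adjusted p = 0.131), respectively. All 16 endothelial markers had positive fold changes, 2 rose and 13 did so over the list alone (median 0.66, adjusted p = 0.223 with an estimated correlation). Acinar markers summed to 1830.3 and 2672 CPM with DMSO and 518 and 465 CPM with DMXAA, with no member past the test (median -2.76, list adjusted p = 0.317 with an estimated correlation).

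None of these calls in knockout-labelled islets was firm. All 20 named genes lost their call in at least 1 fit that left out a library. The count of 64 fell to 3 and 6 without DMSO replicate 1 or 2 and to 14 and 21 without DMXAA replicate 1 or 2. It rose to 116 and 129 without wild-type DMSO replicate 1 or 2, whose spread enters the shared fit. It was 154 with DESeq2 (94 higher and 60 lower) and 129 in a fit of these 4 libraries alone (49 and 80). The older form of the edgeR test gave 29 (16 and 13), so the majority of lower genes was not stable. The count was 0 with limma-voom or with the stricter filter on low counts. With the acinar sum as a covariate, chosen after the data were seen, it was 9, all higher and 0 of them among the 64, and all 20 named calls were lost. The acinar sums did not overlap between these groups (1830.3 and 2672 against 518 and 465 CPM). The covariate is thus hard to separate from the treatment, and this loss says little about the calls. With the covariate the log2 fold change of Kcnj2 was 2.21 (SE 0.53 against 0.33 before), that of Kdr 0.89 (SE 0.22 against 0.15) and that of Ms4a1 -2.84 (SE 1.78 against 0.84). Camera called 10 lists, and 0 with an estimated correlation.

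The third comparison tested the difference between these effects directly. The DMXAA effect differed between genotype labels in 204 genes, 114 with a more positive and 90 with a more negative effect in knockout-labelled islets. Of 50 interferon-stimulated genes 26 had a more negative effect, 46 over the list alone, with a median difference of -2.09 (adjusted p = 0.0188 with an estimated correlation). Oasl1 (-4.94, SE 0.28, adjusted p = 1.85e-06), Ifit1 (-4.91), Ifit3 (-5.15) and Cxcl10 (-7.12) were among them or among the cytokines, of which 8 of 24 were called (adjusted p = 0.00386 with an estimated correlation). Ccl4 differed by -7.59, Ccl3 by -5.86 and Ripk3 by -4.25. The NF-kB inhibitors Tnfaip3 and Nfkbia differed by -2.69 and -1.78 (list adjusted p = 0.0428 with an estimated correlation). The NF-kB list was already higher in knockout-labelled than in wild-type DMSO islets (median 0.45, 9 of 21 over the list alone, adjusted p = 0.313 with an estimated correlation). With DMXAA its median in knockout-labelled islets was -0.22 (adjusted p = 0.317 with an estimated correlation), so the difference need not come from the wild-type rise alone. Among feedback genes, 4 of 12 called, Cd274 differed by -1.70 (list adjusted p = 0.0188 with an estimated correlation). Ifnb1 had a difference of -10.41 with an SE of 5.46 (adjusted p = 0.632), since 6 of the 8 libraries held at most 3 counts, and the genotype comparison under DMXAA below is the firmer test for that gene.

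Among the 114 positive differences, Kcnj2 differed by 4.76 (SE 0.48, adjusted p = 0.000399), Dusp6 by 3.10, the connexin gene Gja1 by 2.79, Chst1 by 3.42 and Apln by 3.48. Kcnj2 was already lower by 1.97 in knockout-labelled than in wild-type DMSO islets. Its difference thus need not come from the wild-type fall alone. Of 16 endothelial markers 7 were called and 15 over the list alone, with a median of 1.14 (adjusted p = 0.0771 with an estimated correlation). Fibroblast markers had a median of 1.26 (1 of 16 called, adjusted p = 0.143 with an estimated correlation), macrophage markers 0.96 (1 of 23, adjusted p = 0.313) and acinar markers -1.90 (0 of 21, adjusted p = 0.474). The p53 target Plk2 differed by 2.17. No islet transcription factor, secretion gene or beta cell marker was called by edgeR, and Pax6 differed by -0.23 (SE 0.21, adjusted p = 0.809), Gcg by -0.02 (adjusted p = 0.99), Ins1 by -0.49 (0.79), Ins2 by -0.12 (0.965), Adgre1 by 1.78 (0.16) and Sting1 by -0.03 (0.994). Across the whole comparison camera called 13 lists, of which 4 held with an estimated correlation. The count of 204 was 117 without wild-type DMXAA replicate 1 (45 more positive and 72 more negative), 94 without knockout-labelled DMSO replicate 1 (39 and 55), 87 without its replicate 2 (27 and 60), and 312 with DESeq2. Without wild-type DMSO replicate 2 (148 and 156) or knockout-labelled DMXAA replicate 1 (83 and 121), and with the acinar covariate chosen after the data were seen (145 and 148), the more negative effects were also the larger part, so the majority of positive differences was not stable.

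Genes that changed in the wild type were followed into the knockout-labelled islets, whose libraries are separate. The 189 raised genes had a median log2 fold change of 1.93 in the wild type and 0.10 in the knockout-labelled islets (quartiles -0.23 and 0.45), which lay above all 10000 random gene sets of matched expression (random median 0.00). In the knockout-labelled islets 1 of these genes was called in the same direction and 1 in the opposite direction. The 64 lowered genes had medians of -1.25 and 0.66, the latter also above all 10000 random sets, so this position is not particular to the raised genes. The random sets were drawn gene by gene and do not allow for genes that vary together. Their medians thus spread too little, and the position does not show a residual response. Of the lowered genes 5 rose in the knockout-labelled islets. Called differences between genotypes are not counted within these sets, since their choice by the wild-type effect favours them. Leaving out knockout-labelled DMSO replicate 1 or 2 moved the median of the raised genes to 0.25 or 0.00. Across all 17055 genes, which are not independent replicates, the effects in the genotypes correlated with r = 0.14 and rho = 0.05, and r was -0.05 without wild-type DMSO replicate 1.

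**Figure D2:**
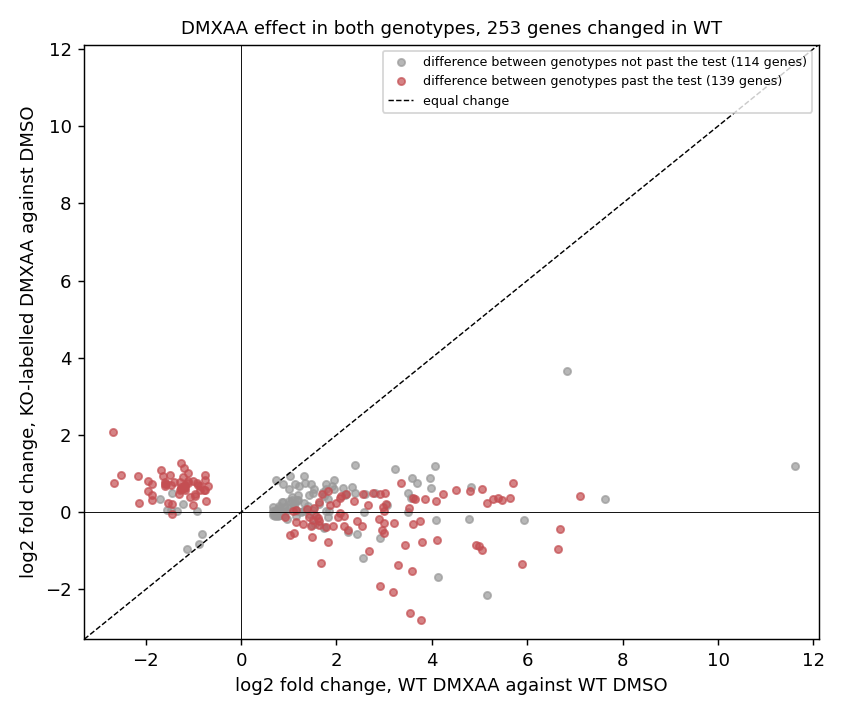
Log2 fold change with DMXAA in wild-type islets (horizontal axis) and in knockout-labelled islets (vertical axis) for the 253 genes changed in the wild type, in red where the difference between genotypes passed the test (139 genes, a share favoured by the choice of genes on the wild-type effect). On the vertical axis the points run from -2.79 to 3.67, the dashed line marks equal change, and 60 of the 64 lowered genes sit above 0. The point at 11.61 is Ifnb1, whose fitted value depends on 0 counts in the wild-type DMSO libraries.

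The fourth comparison set the genotype labels against each other under DMSO. Of the lists, 2 of 13 lymphocyte markers, 1 of 26 stress response genes and 1 of 21 genes of the xenobiotic and NRF2 response were higher in the knockout-labelled islets, and 1 of 16 fibroblast markers was lower. Interferon-stimulated genes had a median of -0.35, with 1 of 50 higher and 5 lower over the list alone, and camera called the list downward (adjusted p = 0.485 with an estimated correlation). The largest rises included Ighg2c at 15.2 ± 6.64 against 0.0772 ± 0.0396 CPM, the antigen presentation gene H2-Eb2 at 2.24 ± 0.0418 against 0.0526 ± 0.0744 CPM and Fcmr, a receptor for IgM, at 4.35 ± 0.0179 against 0.407 ± 0.0193 CPM. Lymphocyte markers had a median log2 difference of 2.57, with 2 of 13 called and 8 over the list alone (adjusted p = 0.254 with an estimated correlation). Hmox1, the heme-degrading enzyme of the oxidative stress response, was at 609 ± 40.9 against 209 ± 25.8 CPM (log2 difference 1.54, SE 0.21, adjusted p = 0.00984), the only member called of 21 in its list (list adjusted p = 0.254 with an estimated correlation). The stress gene Ddit3 was at 193 ± 6.13 against 96.4 ± 12.9 CPM, and the interferon regulator Irf1 was higher by 0.97. Kcnj2 fell by 1.97, the matrix genes Ltbp2 and Col6a3 by 1.64 and 1.22, and Rgs5, a pericyte gene, by 0.98 in the knockout-labelled islets relative to the wild type. Without knockout-labelled DMSO replicate 2 the adjusted p was 0.129 for H2-Eb2, 0.159 for Fcmr and for Hmox1, 0.317 for Ddit3, 0.624 for Kcnj2 and for Col6a3, 0.495 for Ltbp2 and 0.514 for Rgs5. It was 0.294 for Irf1 without knockout-labelled DMSO replicate 1 and 0.254 for Ighg2c without wild-type DMSO replicate 1. With the acinar sum as a covariate, chosen after the data were seen, Kcnj2 was at -1.92 (SE 0.37 against 0.33 before, adjusted p = 0.0916) and Rgs5 at -0.91 (SE 0.17 in both fits, adjusted p = 0.0536). Endothelial markers had a median of -0.25, with 0 of 16 called (list adjusted p = 0.485 with an estimated correlation). Ins1 and Ins2 differed by 0.61 and 0.44 (adjusted p = 0.429 and 0.576), Gcg by 0.37 (0.482), Pax6 by 0.16 (0.674), Adgre1 by -0.49 (0.576) and Cxcl10 by 0.50 (0.616).

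In all 38 genes differed, 31 higher and 7 lower, against 2092 with an unadjusted p under 0.05. Of the 31 higher genes 16 were also among the 36 lower with DMXAA in knockout-labelled islets. Both contrasts and the interaction use the same knockout-labelled DMSO libraries, so their results are not independent. Each of the 20 named genes lost its call in at least 1 fit without a library. The count was 3 and 6 without knockout-labelled DMSO replicate 1 or 2, 24 and 240 without wild-type DMSO replicate 1 or 2, and 94 and 80 without knockout-labelled DMXAA replicate 1 or 2. It was 155 with DESeq2, 13 with limma-voom, 17 with the older edgeR test and 7 with the stricter filter. Camera called 9 lists, and 0 with an estimated correlation.

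The fifth comparison set the genotype labels against each other under DMXAA. In the main fit it gave the largest count of the 5, with 407 genes, 174 higher and 233 lower in the knockout-labelled islets. With the acinar covariate it did not, with 181 against 255 for DMXAA in the wild type and 293 for the interaction. Interferon-stimulated genes were lower in 45 of 50 cases, 48 over the list alone, with a median of -2.28 (adjusted p = 0.00746 with an estimated correlation). Ifnb1 was at 0.0726 ± 0.103 against 21.2 ± 10.8 CPM (log2 difference -7.94, SE 0.67, adjusted p = 6.92e-06). Cytokine genes were lower in 12 of 24 cases (adjusted p = 0.00392 with an estimated correlation), with Cxcl10 lower by 6.61 and the apoptosis ligand gene Tnfsf10 by 2.17 on the log2 scale, as were 6 of 12 feedback genes (adjusted p = 0.0241 with an estimated correlation). Endothelial markers were higher in 10 of 16 cases, 15 over the list alone (median 0.75, adjusted p = 0.108 with an estimated correlation), with Egfl7, an endothelial matrix gene, higher by 1.89, Kdr by 1.11 and Eng by 1.11. With the acinar sum as a covariate, chosen after the data were seen, the log2 differences were 1.44 for Egfl7 (SE 0.34 against 0.23 before, adjusted p = 0.0736), 1.02 for Kdr (SE 0.23 against 0.15, adjusted p = 0.057) and 0.88 for Eng (SE 0.23 against 0.15, adjusted p = 0.0955), with somewhat smaller folds and wider errors, and the calls were lost. Fibroblast markers were higher as well, with 3 of 16 called and a median of 0.82 (adjusted p = 0.222 with an estimated correlation). Of 23 macrophage markers 4 were higher (adjusted p = 0.222 with an estimated correlation). Their sums were 179 and 296 CPM in knockout-labelled DMXAA replicate 1 and 2 against 132 and 135 CPM in the wild type. Without knockout-labelled DMXAA replicate 2 the calls of the macrophage markers Laptm5 (adjusted p = 0.118) and Trem2 (adjusted p = 0.193) were lost. Itgax was higher by 1.41, a call lost without wild-type DMXAA replicate 1 (adjusted p = 0.11) and with the acinar covariate, where the difference was 1.63 (SE 0.39 against 0.25 before, adjusted p = 0.0706). Adgre1 differed by 1.29 (SE 0.36, adjusted p = 0.0944), and it passed the test without knockout-labelled DMXAA replicate 1 (adjusted p = 0.031). Gcg differed by 0.35 (adjusted p = 0.521), Pax6 by -0.06 (0.895), Ins1 by 0.12 (0.905) and Ins2 by 0.32 (0.707).

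Among genes of secretion, 2 of 38 were lower under DMXAA in the knockout-labelled islets. They were Gipr, the receptor of the incretin GIP, at 102 ± 7.76 against 185 ± 22 CPM, and Unc13a, a vesicle priming gene, at 114 ± 41.5 against 211 ± 0.29 CPM. The call of Gipr was lost without wild-type DMXAA replicate 1 (adjusted p = 0.234) or knockout-labelled DMXAA replicate 2 (adjusted p = 0.113), and that of Unc13a without any of 7 of the 8 libraries, with adjusted p up to 0.227. Hmox1 was again higher, by 1.29, and Mt2, a metal-binding protein gene, by 1.19. Their calls were lost without wild-type DMXAA replicate 1 (adjusted p = 0.0693) and replicate 2 (adjusted p = 0.0929). The median of their list was 0.37 (adjusted p = 0.0569 with an estimated correlation). Acinar markers summed to 492 ± 37.8 CPM in the knockout-labelled and 2547 ± 1068 CPM in the wild-type libraries, with no member called (list adjusted p = 0.222 with an estimated correlation). The count of 407 was 616 with DESeq2, 205 without wild-type DMXAA replicate 1, 674 without knockout-labelled DMXAA replicate 1 and 254 without its replicate 2. It was 181 with the acinar sum as a covariate, an alternative chosen after the data were seen, which ended 30 of the 59 named calls. The acinar sums did not overlap between these groups either, so the covariate is hard to separate from the genotype labels there. The fold changes of Unc13a (-1.04, SE 0.35 against 0.21 before, adjusted p = 0.197), Hmox1 (1.29, SE 0.36 against 0.21, adjusted p = 0.116) and Mt2 (1.38, SE 0.31 against 0.20, adjusted p = 0.0604) did not shrink there, and their calls ended through wider errors. Camera called 14 lists, of which 3 held with an estimated correlation and 8 with fry.

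**Figure D3:**
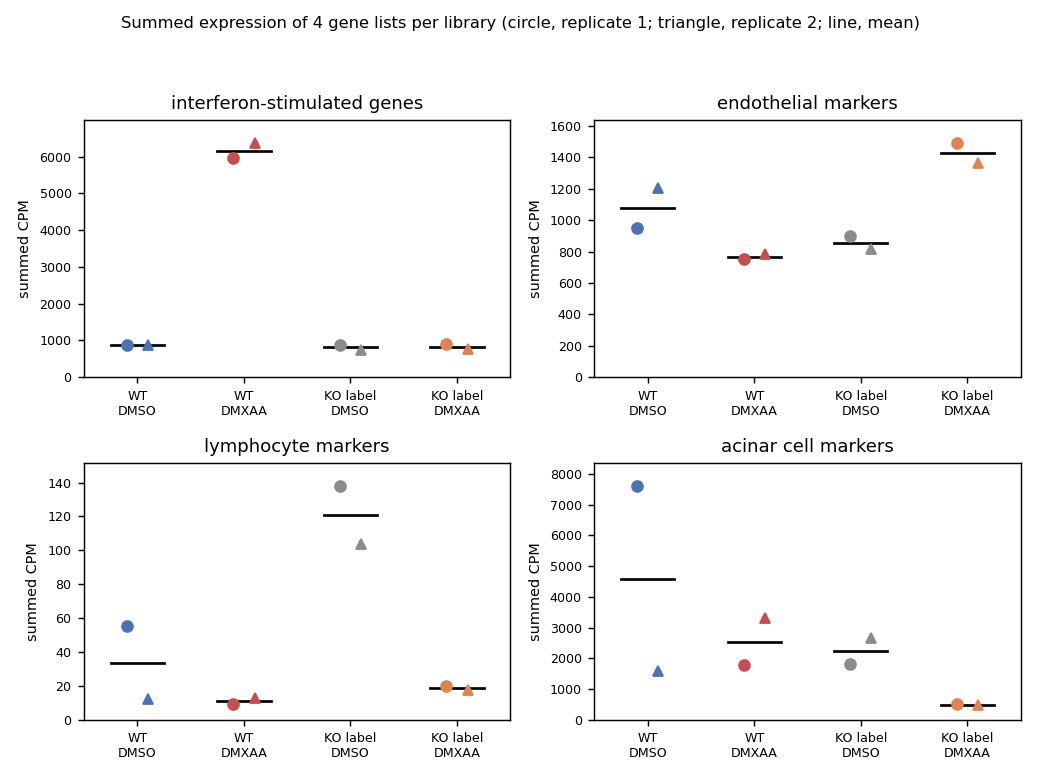
Summed expression in CPM (vertical axes, starting at 0) of 4 gene lists in each library by group (horizontal axes), with a line at the mean of the 2 libraries. Interferon-stimulated genes stood at 6153 CPM in wild-type DMXAA against 875, 809.9 and 829 CPM in the other groups, lymphocyte markers were highest in both knockout-labelled DMSO libraries, and acinar markers ranged from 465 to 7609 CPM.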

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

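The test of the difference between genotypes was planned for every gene. The tests of a lower and a higher endothelial share, of B cells in the knockout-labelled DMSO islets and of wrongly labelled libraries were chosen after the results were seen, and those of T cells and of the DNA around Sting1 before.

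Every result here stood out because the DMXAA effect differed between the genotypes as labelled, by the interaction test over 204 genes. Values are log2 differences, negative where the effect was more negative in the knockout-labelled islets. Cytokine genes were Ccl4 (-7.59), Tnf (-7.22), Cxcl10 (-7.12), Ccl3 (-5.86) and Cxcl1 (-2.81). Interferon-stimulated, DNA-sensing and antigen processing genes were Ifit2 (-6.68), Ifi209 (-6.58), Ifi208 (-6.04), Gbp5 (-5.78), Ifit3 (-5.15), Oasl1 (-4.94), Ifit1 (-4.91), Ifi204 (-2.52) and Tap1 (-1.42). Feedback, NF-kB, cell death, stress and immediate early genes were Acod1 (-4.84), Ripk3 (-4.25), Socs1 (-3.28), Tnfaip3 (-2.69), Nfkbia (-1.78), Cd274 (-1.70), Ppp1r15a (-1.70), Icam1 (-1.63) and Zfp36 (-1.22). Positive differences were found for Kcnj2 (4.76), Apln (3.48), Chst1 (3.42), Dusp6 (3.10), Gja1 (2.79), Kcne3 (2.77), Clec14a (2.61), Gda (2.56), Il7r (2.28), Plk2 (2.17), Tnfrsf10b (1.94), Itgax (1.89), Kdr (1.71), Flt1 (1.55), Vim (1.35), Eng (1.33) and Klf10 (1.18). Some calls were lost in at least 1 fit without a library. They were Tnf, Gbp5, Ifi204, Tap1, Socs1, Icam1, Zfp36, Kcne3, Clec14a, Gda, Il7r, Tnfrsf10b, Itgax, Flt1, Vim, Eng and Klf10. Of these 40 genes 23 kept their call without any 1 library.

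The endothelial markers had a median DMXAA effect of -0.46 in the wild type (3 of 16 fell, adjusted p = 0.237 with an estimated correlation) and 0.66 in the knockout-labelled islets (2 of 16 rose, adjusted p = 0.223 with an estimated correlation), and the list did not hold for the difference (adjusted p = 0.0771 with an estimated correlation). In the wild type the 16 members did not fall by a common factor (Cochran's Q per degree of freedom 3.6, common log2 change -0.49, with 3 members beyond 2 SE of it). This argues against a lower share of a uniform set of endothelial cells as the whole cause. It cannot exclude loss of only some endothelial cells, or markers shared with other cells, since both could give unequal falls. Medians were also negative for fibroblast (-0.60), acinar (-0.89), macrophage (-0.45) and lymphocyte (-1.74) markers, while that of beta cell markers was 0.23. In the knockout-labelled islets all 16 members were positive with Q per degree of freedom 1.06 around 0.68, as a higher share of endothelial cells would give. This does not decide for it, since the positive signs restate the pattern that prompted the test. A response of the cells by a common factor would give the same values. Other cell types moved in the same contrast, with medians of 0.80 for fibroblast markers (15 of 16 positive), 0.46 for macrophage markers (21 of 23 positive) and -2.76 for acinar markers (0 of 21 positive), so a change in the make-up of the islets beyond endothelial cells stays open. A response of the cells themselves to DMXAA stays open under both genotype labels, as a hypothesis. In the wild type a change in share could act alone or together with such a response.

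B cell transcripts were high in both knockout-labelled DMSO libraries. There 8 of 8 B-lineage members were higher in both than in each of the other 6 libraries, with sums of 117 and 86.6 CPM against at most 42.4 CPM, but this restates the pattern and leaves B cells in those islet preparations open. Lymph node tissue with T cells cannot be told apart from B cells alone. The lowest T cell sum of these libraries was 1.9 times the highest of the others, below the 2 times the test asked for. That highest sum, 3.84 CPM in wild-type DMXAA replicate 2, was mostly Lck (3.52 CPM). Cd3e was at 1.28 and 1.19 CPM in the knockout-labelled DMSO libraries and at most 0.16 CPM elsewhere. Cd3d, Cd3g, Cd4 and Cd8b1 were also higher in both, while Cd8a, Cd2, Cd5 and Lck were not. The knockout-labelled DMXAA libraries had B-lineage sums of 6.95 and 8.77 CPM. These lay within the wild-type range of 3.9 to 42.4 CPM, which goes against genotype alone. No biological explanation was tested further.

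Sting1 counts were not lower in the libraries labelled knockout. Wild-type islets treated with DMXAA under knockout DMXAA labels were argued against, since the median change of interferon-stimulated genes there was 0.117 of that in the wild type. That test covers this exchange only. Islets that had not received DMXAA would show the same lack of a rise whatever their genotype, so it does not establish the genotype. Set against wild-type DMSO, these libraries gave 0 called genes of 17055 by the quasi-likelihood test and 169 with DESeq2, which does not settle this. Other DNA around Sting1 cannot be told apart from its absence (Fisher's exact p = 0.196), and few genes lie there. That test counted genes at an unadjusted p under 0.01 between genotype labels, averaged over both treatments. These were 6 of 168 genes within 10 Mb and 1039 of 16887 other genes. At an adjusted p under 0.05 the averaged contrast called 282 genes. It also carries the genotype differences seen under DMXAA. An allele that leaves the transcript in place stays open and was not tested, since counts over whole genes do not show exons.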

How the results depend on the processing

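The acinar covariate was chosen after the data were seen, and all other alternatives were planned. The acinar sums of knockout-labelled DMXAA libraries did not overlap those of knockout-labelled DMSO or wild-type DMXAA libraries. In those contrasts the covariate widens the errors by design and is a weak test. With 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other groups, and it takes away 1 of 4 residual degrees of freedom. At these depths a gene with 0 counts lies below 0.145 to 0.2 CPM per library, so genes of rare cells have wide errors.

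Counts of changed genes moved most under these alternatives, and the cause was not tested. For DMXAA in knockout-labelled islets (64) the counts were 154 with DESeq2, 0 with limma-voom, 29 with the older edgeR test, 177 with no filter, 0 with the stricter filter, 129 with only the libraries compared and 9 with the acinar covariate. For the genotypes under DMSO (38) they were 155 with DESeq2, 13 with limma-voom, 17 with the older edgeR test, 159 with no filter, 7 with the stricter filter and 25 with only the libraries compared. DESeq2 gave 312 for the interaction (204) and 616 for the genotypes under DMXAA (407), where the acinar covariate gave 181. Leaving out 1 library gave 160 to 994 for the wild type (253), 3 to 129 for the knockout-labelled islets, 87 to 304 for the interaction, 3 to 240 for the genotypes under DMSO and 205 to 674 under DMXAA.

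Lists called by camera went from 16 to 3 with an estimated correlation in the wild type (11 with fry). They went from 10 to 0 in the knockout-labelled islets (0 with fry) and from 13 to 4 for the interaction (5 with fry). For the genotypes they went from 9 to 0 under DMSO (0 with fry) and from 14 to 3 under DMXAA (10 with fry, 8 of them shared). In the wild type, fry kept among others NF-kB targets (adjusted p = 0.0182), MHC class I genes (0.0203), cell death genes (0.0203) and endothelial markers (0.0491). An estimated correlation allows for members that vary together. Leaving out 1 library gave 8 to 17 lists for the genotypes under DMSO. The median effect in knockout-labelled islets of genes raised in the wild type (0.10) ran from 0.00 to 0.25 without 1 library. The correlation of effects (0.14) was 0.04 with the stricter filter, and ran from -0.05, reversed, to 0.15 without 1 library. The cause was not tested.

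With the replicate number as a block, counts were 259 for the wild type, 61 for the knockout-labelled islets, 217 for the interaction, 56 for the genotypes under DMSO and 417 under DMXAA. Blocked within genotype the first 3 were 299, 96 and 246, and the genotype contrasts cannot be fitted that way. Lists called with the replicate block were 15, 10, 12, 9 and 13, the median effect was 0.10 and the correlation 0.15. Equal numbers did not deviate together (r between -0.20 and 0.18), and no label pairs them. Such correlations cannot exclude a shared mouse, pool or day, so whether equal numbers are paired is not known. RLE size factors shifted the median over all genes by at most 0.02. No called gene named in the text reversed under any alternative. Of the named genes called, 30 of 52 in the wild type, 0 of 20 in the knockout-labelled islets, 23 of 40 for the interaction, 0 of 20 under DMSO and 32 of 59 under DMXAA kept their call without any 1 library.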

Other observations

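The comparison of knockout-labelled DMXAA with wild-type DMSO libraries was chosen after the data were seen, and the other values come from lists and libraries fixed before.

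Knockout-labelled islets with DMXAA were set against wild-type islets with DMSO. The quasi-likelihood test called 0 of 17055 genes there, with 2458 at an unadjusted p under 0.05. DESeq2 called 169, limma-voom 0 and the older edgeR test 0. The median log2 difference was -0.15 for interferon-stimulated genes and 0.37 for endothelial markers. A p that misses the threshold does not show that these groups were alike, since the groups hold 2 libraries each.

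Fibroblast and stellate cell markers summed to 612 and 456 CPM in wild-type DMSO, 278 and 447 CPM in wild-type DMXAA, 397 and 417 CPM in knockout-labelled DMSO and 679.6 and 668 CPM in knockout-labelled DMXAA libraries. Their median effect of DMXAA was -0.60 in the wild type (adjusted p = 0.37 with an estimated correlation) and 0.80 in the knockout-labelled islets (adjusted p = 0.317 with an estimated correlation). Macrophage markers averaged 175 ± 40.3 and 133 ± 1.85 CPM in the wild type, and 184 ± 1.49 and 238 ± 83 CPM in the knockout-labelled islets. Mitochondrially encoded mRNAs averaged 10521 ± 1957 and 6758 ± 893 CPM in the wild type, and 14329 ± 2288 and 10109 ± 532 CPM in the knockout-labelled islets, each pair given as DMSO and DMXAA.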
